A study of Mus musculus with 12 samples.

How the data were processed

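Total RNA from mouse embryonic fibroblasts that lack KSR1 (genotype KSR1-/-, DBA background strain) was labelled with a 1-cycle kit and hybridised to an Affymetrix mouse array, per the labels' protocols. The arrays covered 4 groups with 3 arrays each. One cell line carried green fluorescent protein (GFP) alone, one carried oncogenic H-RasV12 and GFP, one carried re-expressed KSR1 and GFP, and one carried KSR1, H-RasV12 and GFP. Each cell line was measured in triplicate, per the labels, and nothing states that the arrays of a group came from separate cultures. The p-values therefore measure the spread between arrays of 1 cell line per condition, which may be technical, and not the spread between independently made lines.

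The deposited values are MAS5 signals, per the submitters' processing notes, with the MAS5 version not given in the sources used here. Each deposited value is a probe set's intensity on a linear scale. The authors' scaling left every array with a 2% trimmed mean of 500.3, so no further scaling between arrays was applied. Median signals ran from 160.6 to 216.5. The table held 12488 probe sets, of which 66 were controls and were left out of the tests. Gene names came from the platform annotation, with symbols updated by gene identifier to the GRCm38.p6 gene table, which was used for names alone. Of the other probe sets, 10833 had 1 gene symbol, 396 had several and 1193 were unnamed here. The gene identifiers of 10817 of the probe sets with 1 symbol were found in that table. No genome was used here, so no coordinates are given.

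A pseudocount of 23, the 20th percentile of all values rounded to a whole number, was added before the log2 transformation. Fold changes are therefore on the log2(value + 23) scale, which understates the change of dim probe sets. A probe set was tested when its value exceeded the median of all values, 181.4, on at least 3 of the 12 arrays. This kept 6897 probe sets and left 5525 below the filter. One limma fit (limma 3.58.1 in R 4.3.3) with 4 group means and 8 residual degrees of freedom served all comparisons, with an intensity trend in the empirical Bayes step and two-sided tests. P-values were adjusted by the Benjamini-Hochberg method over the 6897 probe sets, and a probe set was called at an adjusted p under 0.05. The comparisons were H-RasV12 against GFP, KSR1 against GFP, KSR1 with H-RasV12 against KSR1, KSR1 with H-RasV12 against H-RasV12, the interaction (the H-RasV12 response with KSR1 minus the response without it), and both transgenes against GFP. Errors of fold changes are standard errors from limma, and errors of signals are SDs over 3 arrays.

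For gene lists, each gene was represented by the probe set with the highest mean among those with 1 gene symbol, which gave 5288 genes. The 26 lists were written before the data were examined, and the 22 with at least 5 measured genes were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 22 lists within each comparison. The same test with a correlation estimated from the arrays called 0 lists in any of the 6 comparisons. The fry test, which asks whether a list's genes move one way and makes no comparison with other genes, called 0, 12, 15, 13, 10 and 13 lists in the order of comparisons above. Counts of list members refer to adjustment over all 6897 probe sets unless a count adjusted over the list alone is named.

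The genes named in the text were taken by a rule fixed before the data were examined. It names the probe sets of Ksr1, Ppargc1a and Esrra in any case, then for each comparison the 6 highest and 6 lowest log2 fold changes among called genes whose groups do not overlap (no such demand for the interaction), and up to 4 called members with the largest changes from each list. The text describes a selection from that set. Hras and Ppargc1b were also on the rule's list and were not analysed here. For Ppargc1a, which lay below the filter, and for the leukocyte markers, values come from the fit without a filter. Where the lysosome and imprinted gene lists name other members, those were chosen after their values were seen.

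The procedure was tested on simulated data with the spread and means of the 6897 probe sets, in which 100 probe sets were changed by 2-fold and 100 by 4-fold. For H-RasV12 without KSR1 it recovered 57% of the 2-fold and 96% of the 4-fold changes. These shares hold for 200 changed probe sets, and the Benjamini-Hochberg cutoff is stricter where fewer are called. They do not carry over to the real comparison of H-RasV12 without KSR1, which called 5 probe sets. The recovery was 53% and 92% for KSR1 without H-RasV12, 59% and 93% for H-RasV12 with KSR1, 57% and 93% for KSR1 with H-RasV12, 60% and 94% for both transgenes, and 21% and 75% for the interaction. Between 3 and 9 unchanged probe sets were called in a comparison, no change had the wrong sign, and the list raised by 0.75 on the log2 scale was called with 0 other lists. The simulated probe sets varied independently of each other, so this does not show how often lists of correlated genes are called falsely.

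The alternatives tried were other pseudocounts, no filter and a stricter one, quantile normalization, median centring, a fit without the intensity trend, array weights, a fit on the compared groups alone, other thresholds, the replicate number as a block, the estimated correlation, the mean of a gene's probe sets, and each of the 12 arrays left out in turn. Arrays with the same replicate number deviated together from their group means in all 3 pairs for KSR1 against GFP (r from 0.21 to 0.511) and for KSR1 with H-RasV12 against KSR1 (r from 0.162 to 0.432). In these 2 comparisons the numbers were taken to pair the arrays, from the correlations alone, since the labels name no shared day or batch, and the value with the number as a replicate block is given where it changes a call or moves a count in the text by over 1.5 times. An analysis of replicates 2 and 3 alone (8 arrays) was added after the data were seen. Its reason was a low 18S ribosomal RNA control signal on the replicate 1 arrays of the GFP, KSR1 and KSR1 with H-RasV12 groups.

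In the closing section, 2 lists of lysosome and of imprinted genes were written after named genes of these classes had been seen, and the genes already seen were left out of the tests. A first run of these tests had not yet left out Ctsb, Ctsl and Dlk1. It gave a camera p of 2.27e-08 for the lysosome genes and a percentile of 80.43 for the imprinted genes, against 2.33e-08 and 76.82 in the corrected run, which is the one reported.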

Results

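Transcript levels were measured on 12 Affymetrix arrays of mouse embryonic fibroblasts without endogenous KSR1, a scaffold protein of the Raf, MEK and ERK kinase cascade. The 4 cell lines carried GFP alone, the oncogenic Ras mutant H-RasV12, re-expressed KSR1, or KSR1 together with H-RasV12 (the double line), with 3 arrays per line. Levels are mean MAS5 signals ± SD over 3 arrays (n = 3), and changes are log2 fold changes ± SE with adjusted p-values from limma over 6897 probe sets. Values from another fit are named as such. The number of arrays limits the precision. Arrays of one group correlated with r between 0.911 and 0.965 across probe sets, and arrays of different groups with r between 0.808 and 0.956. The first 3 principal components held 37.7%, 24.9% and 10.5% of the variance. The 18S ribosomal RNA control read 344.6, 394.7 and 146.4 on the replicate 1 arrays of the GFP line, the KSR1 line and the double line. It read 1114 on the H-RasV12 replicate 1 array, 515.7 on GFP replicate 3 and between 1130 and 3312 on the other 7 arrays. The control for the 3' end of beta-actin read 7981 on GFP replicate 1 and 8629 on double-line replicate 1. On all other arrays it lay between 16680 and 26873.

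Interrogation of the 2 Ksr1 probe sets showed that one of them followed the labels. Its signal was 67.4 ± 66.5 with GFP and 22.2 ± 9.14 with H-RasV12, and it rose to 915 ± 699 with KSR1 (+3.22 ± 0.62, limma adjusted p = 0.00309). With KSR1 and H-RasV12 it reached 235 ± 83.6, which was above H-RasV12 alone (+2.47 ± 0.62, limma adjusted p = 0.0136, 0.0524 without double-line replicate 2 and up to 0.0598 over the alternatives) but did not differ from GFP alone past the threshold (limma adjusted p = 0.0835). The KSR1 arrays varied widely, at 933.4, 1605 and 207.3. The double-line mean lay below the KSR1 mean, although the KSR1 array at 207.3 lay below both. Differences between these 2 lines may therefore also reflect the level of KSR1, which was not tested. The other probe set stayed between 199.7 and 294.1 in the group means and passed no test. Which part of the transcript each probe set covers was not analysed here. Of the sex-linked genes, Kdm5d, Eif2s3y and Uty of the Y chromosome stayed at group means between 7.66 and 31.5, below the filter. Xist, the RNA of the inactive X chromosome, was present at 736 ± 399, 671 ± 185, 190 ± 116 and 693 ± 340 in the GFP, H-RasV12 and KSR1 lines and the double line. It was lower with KSR1 than with GFP (-1.83 ± 0.42, limma adjusted p = 0.0106), a call that ended without GFP replicate 2 (0.0545) or KSR1 replicate 2 (0.0586).

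The comparison of H-RasV12 with GFP asked what oncogenic Ras changes in cells that lack KSR1. Of 6897 probe sets, 5 fell, 0 rose and 411 had an unadjusted p under 0.05. Ccn5, a matricellular protein of the CCN family, fell from 1722 ± 427 to 221 ± 69.6 (-2.85 ± 0.27, limma adjusted p = 0.000306) and kept its call in all 23 alternatives. The collagen-binding proteoglycan Fmod fell by 3.04 ± 0.47 on the log2 scale, as did the soluble pattern recognition gene Ptx3 (-2.06 ± 0.31) and the smooth muscle actin gene Actg2 (-1.61 ± 0.23, limma adjusted p = 0.0228 each). Amotl2, an angiomotin family member, fell by 1.38 ± 0.22 (limma adjusted p = 0.0246). The last 4 lost their calls in 7, 5, 4 and 7 of the alternatives in that order, each without GFP replicate 2, GFP replicate 3 or H-RasV12 replicate 2 (limma adjusted p between 0.121 and 0.164). Fmod, Ptx3 and Amotl2 also lost theirs without H-RasV12 replicate 3 (0.147 each), and Amotl2 without KSR1 replicate 2 (0.0554) or double-line replicate 2 (0.0535). The count moved to 23 without GFP replicate 1, 13 without H-RasV12 replicate 1, 2 without H-RasV12 replicate 3, and 1 without each of GFP replicate 2, GFP replicate 3 and H-RasV12 replicate 2. With replicates 2 and 3 alone, an alternative chosen after the data were seen, 53 probe sets were called. The 5 genes of the full fit were also lower for KSR1 against GFP, 4 of them past the threshold. Their median log2 fold change was -2.34 there and -2.06 with H-RasV12. Both comparisons share the GFP arrays, so a high level in the GFP line cannot be told apart from a fall with H-RasV12.

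Among the ERK targets and feedback regulators 0 of 17 measured genes were called for H-RasV12 without KSR1, and the list did not pass (camera adjusted p = 0.941). The smooth muscle and SRF-regulated cytoskeleton genes were lower as a list (camera adjusted p = 3.77e-06, adjusted p = 0.223 with an estimated correlation), with 1 of 18 called, Actg2, and 5 adjusted over the list alone. This count was 4 without GFP replicate 1, 0 without GFP replicate 2, GFP replicate 3 or H-RasV12 replicate 2, and 4 with replicates 2 and 3 alone. The p53 targets and cell cycle inhibitors were lower as a list (camera adjusted p = 0.000161, adjusted p = 0.223 with an estimated correlation) with 0 of 12 called, and 1 higher and 1 lower adjusted over the list alone. Without GFP replicate 1 it had 1 lower gene, and 2 with replicates 2 and 3 alone. Glycolysis, hypoxia-response and collagen lists were lower and the interferon list higher (camera adjusted p = 0.0314 each, adjusted p = 0.726 with an estimated correlation), with 1 called member among them, Fmod, and 4 lower and 1 higher collagen genes adjusted over the list alone. Leaving out GFP replicate 1 or H-RasV12 replicate 1 ended the calls for glycolysis (camera adjusted p = 0.491 and 0.331) and hypoxia (0.275 and 0.0691). Leaving out GFP replicate 2, GFP replicate 3 or H-RasV12 replicate 2 ended that for collagens (0.111, 0.2 and 0.655). The collagen list had 0 genes called without any 1 of those 3 arrays or H-RasV12 replicate 3, and 3 with replicates 2 and 3 alone. The interferon call ended without GFP replicate 2, GFP replicate 3 or H-RasV12 replicate 1 (0.395, 0.0951 and 0.85) and after quantile normalization (0.0652). With replicates 2 and 3 alone the glycolysis, hypoxia and interferon calls ended (0.94, 0.304 and 0.104).

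Other lists missed the threshold for H-RasV12 without KSR1 and passed it in some alternatives, with 0 members called in each. Oxidative phosphorylation (0.169) was lower without GFP replicate 1 (camera adjusted p = 0.000804) or H-RasV12 replicate 3 (0.0428) and with replicates 2 and 3 alone (0.0021). S phase genes (0.186) were higher without GFP replicate 1 (0.032) or H-RasV12 replicate 1 (0.0303) and with replicates 2 and 3 alone (0.00308). Mitosis genes (0.205) were higher without GFP replicate 2 (0.0456) or H-RasV12 replicate 1 (0.0191). The growth factors, cytokines and chemokines (0.0891) were lower without GFP replicate 3 (0.0275) or H-RasV12 replicate 3 (0.0442), and fatty acid oxidation genes (0.157) without H-RasV12 replicate 1 (0.0353).

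KSR1 was compared with GFP to ask what re-expression of the scaffold changes without oncogenic Ras. Of 6897 probe sets 343 rose and 470 fell, and 1714 had an unadjusted p under 0.05. Among the called probe sets 76 rose and 101 fell by at least 4-fold. The muscle ankyrin repeat gene Ankrd1 rose from 25.4 to 2745 ± 378 (+5.84 ± 0.47, limma adjusted p = 2.87e-06), the peptide hormone gene Cck from 10.8 ± 5.07 to 2027 ± 1255 (+5.74 ± 0.47, limma adjusted p = 3.31e-06), and the mesothelial antigen Msln from 19 ± 9.08 to 1405 ± 466 (+5.06 ± 0.37). Gap43, a growth cone protein, rose from 107 ± 12.7 to 2876 ± 358 (+4.48 ± 0.23, limma adjusted p = 3.49e-08). In the other direction the matricellular protein gene Postn fell from 2569 ± 1027 to 15.8 ± 12.6 (-6.03 ± 0.37), the chemokine gene Cxcl12 from 3111 ± 887 to 39.9 ± 13.4 (-5.62 ± 0.31) and Thbs2, which encodes a thrombospondin, from 4149 ± 1229 to 80.9 ± 9.80 (-5.29 ± 0.41). The Wnt antagonist gene Sfrp2 (-4.78 ± 0.41) and the actin-binding protein gene Tagln (-4.51 ± 0.39) fell as well. The count was 482 without GFP replicate 3 and 512 without KSR1 replicate 2.

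Of the collagens and extracellular matrix genes 18 of 34 fell with KSR1, 2 rose (Col18a1 and Col8a1) and 14 did not pass, with 18 lower and 3 higher adjusted over the list alone (camera adjusted p = 1.93e-10, adjusted p = 0.184 with an estimated correlation). Col4a1, a basement membrane collagen, fell from 1597 ± 162 to 169 ± 78.7 (-3.16 ± 0.28), and the fibrillar collagen gene Col3a1 fell by 1.79 ± 0.28. Of the growth factors, cytokines and chemokines of Ras-transformed cells 8 of 15 rose and 0 fell, also 8 adjusted over the list alone (camera adjusted p = 1.51e-05, adjusted p = 0.117 with an estimated correlation). The chemokine gene Cxcl1 rose by +3.60 ± 0.65, Cxcl2 by +3.48 ± 0.47, the epidermal growth factor receptor ligand Ereg from 275 ± 97.5 to 2977 ± 423 (+3.38 ± 0.52), and the prostaglandin synthase gene Ptgs2 by +3.07 ± 0.41. Of 17 ERK targets 4 rose, against 5 adjusted over the list alone and 7 without double-line replicate 1 (camera adjusted p = 0.000489, adjusted p = 0.212 with an estimated correlation). Ier3 rose by +2.49 ± 0.27 and Plaur, the urokinase receptor, by +1.77 ± 0.24.

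Further lists changed in part with KSR1 alone. Of the mesenchymal and epithelial state genes 5 of 12 rose and 1 fell, also 5 and 1 adjusted over the list alone (camera adjusted p = 0.00488, adjusted p = 0.117 with an estimated correlation). Those that rose included the epithelial tight junction gene Cldn3 (+2.06 ± 0.31) and the mesenchymal transcription factor genes Prrx1 (+1.43 ± 0.27) and Twist2 (+1.31 ± 0.22), and the transcription factor gene Snai2 fell by 1.49 ± 0.23. The S phase and DNA replication list was higher (camera adjusted p = 1.51e-05, adjusted p = 0.368 with an estimated correlation) with 2 of 26 called and 0 adjusted over the list alone. This count was 0 without GFP replicate 1, GFP replicate 2, GFP replicate 3, KSR1 replicate 2 or KSR1 replicate 3, 1 without H-RasV12 replicate 1 or H-RasV12 replicate 3 and under median centring, and 4 without double-line replicate 3. The mitosis list was higher with 2 of 26 called, 2 adjusted over the list alone, among them the spindle midzone gene Prc1 (+1.24 ± 0.22, camera adjusted p = 0.0275, adjusted p = 0.589 with an estimated correlation), and this call ended without GFP replicate 1, GFP replicate 3 or KSR1 replicate 3 (0.0743, 0.091 and 0.0781) and with replicates 2 and 3 alone (0.0585). The mitosis list had 1 gene called without GFP replicate 3, KSR1 replicate 1 or KSR1 replicate 2. The p53 list was lower with 1 of 12 called (Gadd45a, camera adjusted p = 0.00488, adjusted p = 0.241 with an estimated correlation), and 4 were lower adjusted over the list alone. Its count was 6 without GFP replicate 1, 2 without KSR1 replicate 3 or double-line replicate 1 and after quantile normalization, and 4 with replicates 2 and 3 alone.

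Of 12 interferon response genes 3 fell, 7 and 1 higher adjusted over the list alone, with Ifi35 at -2.15 ± 0.35 (camera adjusted p = 0.00433, adjusted p = 0.368 with an estimated correlation), 1 without KSR1 replicate 3 and 5 without GFP replicate 2, after quantile normalization or with the replicate block. Fatty acid oxidation genes were lower with 3 of 16 called, also 3 adjusted over the list alone, with the dienoyl-CoA reductase gene Decr1 at -1.67 ± 0.23 (camera adjusted p = 0.0209, adjusted p = 0.368 with an estimated correlation), a call that ended without GFP replicate 1 or KSR1 replicate 3 (0.0683 and 0.0781), and 1 gene passed without GFP replicate 3 or KSR1 replicate 2. The adipocyte list was higher with 3 of 12 called higher and 1 lower, 6 and 2 adjusted over the list alone (camera adjusted p = 0.0253, adjusted p = 0.201 with an estimated correlation), and ended without GFP replicate 2 or KSR1 replicate 1 (0.0516 and 0.0596) and with replicates 2 and 3 alone (0.0652). It had 5 genes higher with the replicate block and 2 lower without double-line replicate 1. The smooth muscle and SRF-regulated list missed the threshold (0.0517) with 5 of 18 lower and 1 higher (Ankrd1), 7 and 1 adjusted over the list alone. It was lower past it without GFP replicate 1, H-RasV12 replicate 2, H-RasV12 replicate 3 or KSR1 replicate 3 (0.00505, 0.0497, 0.0464 and 0.0284) and with replicates 2 and 3 alone (0.0161). The unfolded protein and ATF4 response list also missed it (0.0517) and was lower past it with the replicate block (0.0491) and without GFP replicate 3, H-RasV12 replicate 1, H-RasV12 replicate 3 or KSR1 replicate 3 (0.0327, 0.0463, 0.0462 and 0.0489). The lists for oxidative phosphorylation (0.126), the tricarboxylic acid cycle (0.946), glycolysis (0.454) and hypoxia (0.277) did not pass with KSR1 alone, except that oxidative phosphorylation was lower without GFP replicate 1 (0.0163) or KSR1 replicate 3 (0.0128).

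**Figure D1:**
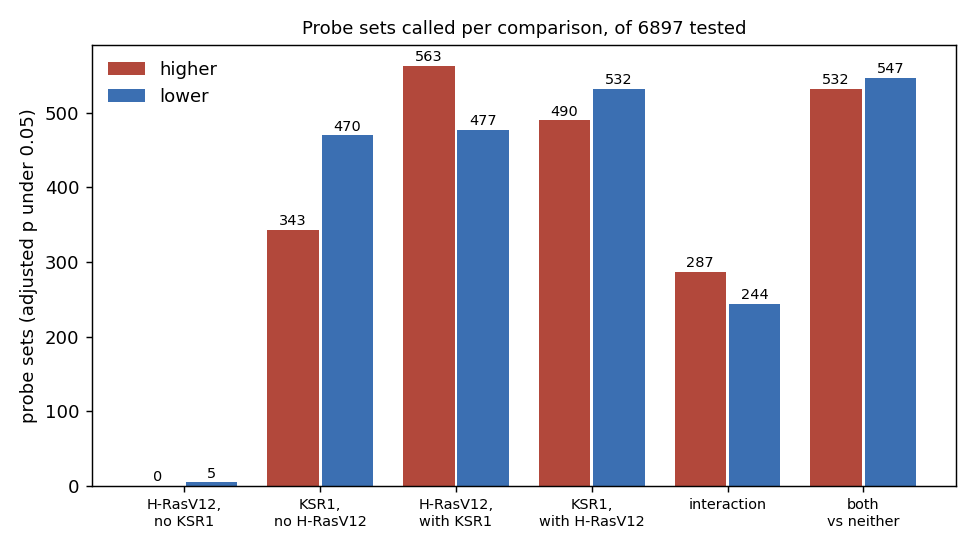
Bars give the number of probe sets called higher (red) and lower (blue) in each of 6 comparisons at a limma adjusted p under 0.05, of 6897 tested. H-RasV12 without KSR1 called 5 and H-RasV12 with KSR1 called 1040.

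H-RasV12 was then compared in the presence of KSR1. Of 6897 probe sets 563 rose and 477 fell, and 1888 had an unadjusted p under 0.05. Chchd10, a mitochondrial intermembrane space protein, rose from 248 ± 130 to 10099 ± 1146 (+5.37 ± 0.35, limma adjusted p = 2.62e-07). The vasodilator peptide gene Adm rose by +4.75 ± 0.49, the lysosomal membrane glycoprotein gene Cd68 from 150 ± 10.6 to 4012 ± 1023 (+4.51 ± 0.22, limma adjusted p = 1.57e-08), the cysteine protease gene Ctsk from 255 ± 222 to 4295 ± 462 (+4.23 ± 0.50) and the imprinted zinc finger gene Peg3 by +4.16 ± 0.57. Among the genes that fell were the water channel gene Aqp1, from 2280 ± 268 to 13.1 ± 3.18 (-5.99 ± 0.33, limma adjusted p = 6.00e-08), Cck (-5.96 ± 0.47), Gap43 (-5.12 ± 0.23), the activin antagonist Fst (-4.86 ± 0.41) and the ubiquitin hydrolase gene Uchl1 (-4.71 ± 0.26).

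Genes of oxidative metabolism rose together with H-RasV12 in the presence of KSR1. Of 44 oxidative phosphorylation subunits 28 rose and 0 fell, and 35 rose adjusted over the list alone (camera adjusted p = 6.49e-15, adjusted p = 0.078 with an estimated correlation). The complex I subunit gene Ndufs3 rose from 1203 ± 139 to 3061 ± 495 (+1.32 ± 0.17), the ATP synthase subunit gene Atp5o by +1.29 ± 0.18 and the complex II subunit gene Sdhd by +1.28 ± 0.18. Of 16 tricarboxylic acid cycle genes 12 rose and 0 fell, 13 adjusted over the list alone (camera adjusted p = 1.11e-08, adjusted p = 0.0607 with an estimated correlation), among them the pyruvate dehydrogenase subunit gene Pdhb (+1.61 ± 0.20) and the malate dehydrogenase gene Mdh2 (+0.98 ± 0.18). Of 16 fatty acid oxidation genes 10 rose and 0 fell, also 10 adjusted over the list alone (camera adjusted p = 7.22e-07, adjusted p = 0.078 with an estimated correlation), with Hadhb, a trifunctional protein subunit, at +1.70 ± 0.18 and the thiolase gene Acaa2 at +1.58 ± 0.19. The oxidative phosphorylation count was 16 without KSR1 replicate 1, 18 without KSR1 replicate 2 and 16 without double-line replicate 2. It was 20 with replicates 2 and 3 alone, which leave out the arrays with the low 18S control.

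Glycolysis and hypoxia-response genes rose as well. Of 17 glycolysis and glucose uptake genes 10 rose and 0 fell, 12 adjusted over the list alone (camera adjusted p = 4.43e-08, adjusted p = 0.078 with an estimated correlation). The phosphofructokinase gene Pfkp rose from 420 ± 66.1 to 3261 ± 721 (+2.88 ± 0.20), Eno2 by +2.04 ± 0.31 and the glucose transporter gene Slc2a1 by +1.83 ± 0.41. The glycolysis count was 6 without KSR1 replicate 3 and 5 without double-line replicate 2. Of 12 hypoxia-response genes 7 rose and 0 fell, 9 adjusted over the list alone (camera adjusted p = 7.22e-07, adjusted p = 0.109 with an estimated correlation). The endoplasmic reticulum oxidase gene Ero1a rose from 1518 ± 417 to 11246 ± 4263 (+2.84 ± 0.28), Ndrg1 by +2.72 ± 0.31 and the mitophagy receptor gene Bnip3 by +2.07 ± 0.46. The list of PGC-1 and ERR regulators of metabolism had 0 of 5 called (camera adjusted p = 0.749, adjusted p = 0.791 with an estimated correlation). It had 1 gene higher without GFP replicate 1, GFP replicate 2 or KSR1 replicate 1, under median centring and with the replicate block, 2 higher after quantile normalization, 1 lower without double-line replicate 1, and 1 each way with replicates 2 and 3 alone. Esrra, which encodes the orphan nuclear receptor ERRα, passed at its dimmer probe set (128 ± 44.3 to 415 ± 63.2, +1.56 ± 0.31, limma adjusted p = 0.00284) but not at its brighter one (+0.89, limma adjusted p = 0.0598, and 0.0174 with the replicate block). Ppargc1a, which encodes the coactivator PGC-1α, was at 17.4 ± 10.5 with KSR1 and 109 ± 50.6 with KSR1 and H-RasV12 (+1.66 ± 0.31, limma adjusted p = 0.00467 without a filter).

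**Figure D2:**
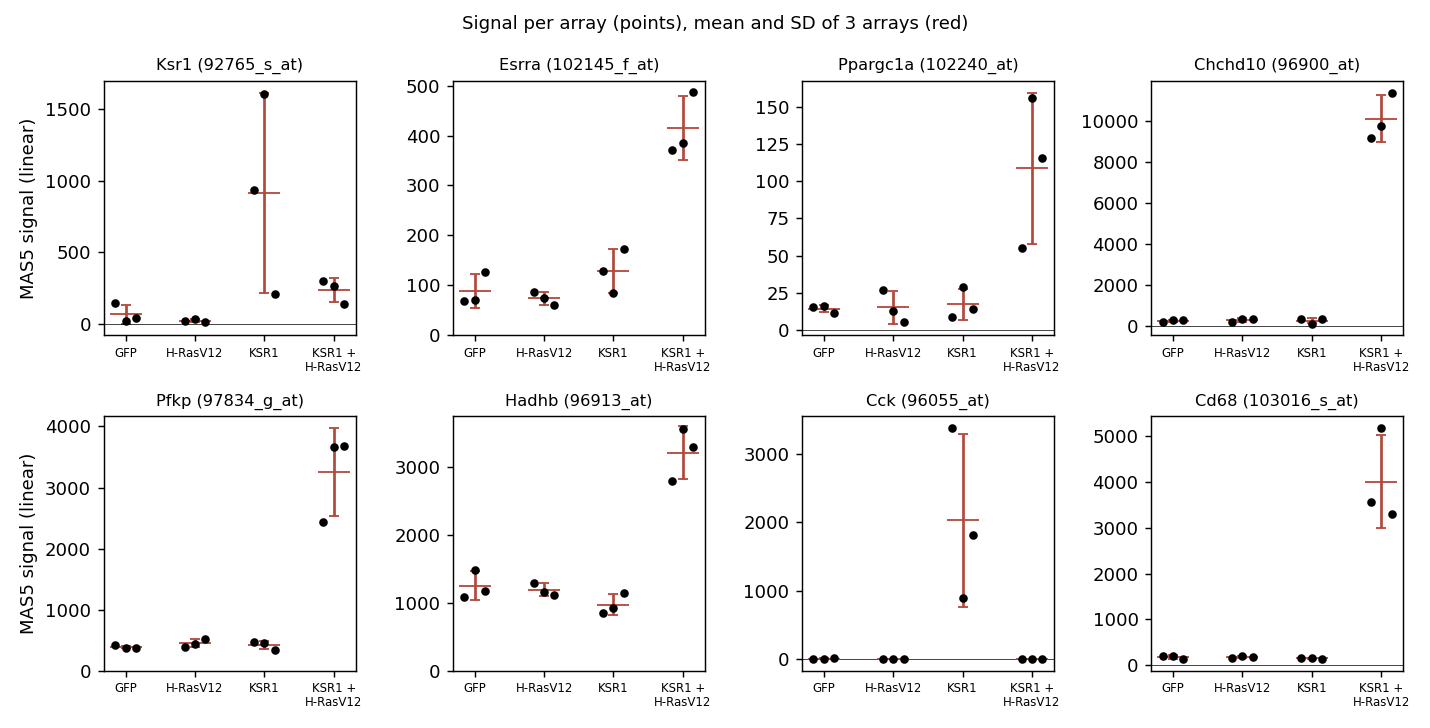
Points are MAS5 signals (linear scale) of single arrays in the 4 cell lines, with the mean and SD of 3 arrays in red, for Ksr1, Esrra, Ppargc1a, Chchd10, Pfkp, Hadhb, Cck and Cd68. Of the named probe sets of a gene, the one with the lowest limma p for KSR1 with H-RasV12 is shown. Ksr1 is therefore shown by the probe set that followed the labels, and Esrra by its dimmer one. The Chchd10 mean was 10099 with KSR1 and H-RasV12 and 248 with KSR1 alone, and the Cck mean was 2027 with KSR1 alone and 5.70 with both.

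ERK targets and secreted factors moved downward in the double line against the KSR1 line. These are separate lines that also differed in mean Ksr1 signal. Of 17 ERK targets 8 fell and 0 rose, 10 adjusted over the list alone (camera adjusted p = 3.31e-05, adjusted p = 0.0934 with an estimated correlation). The receptor tyrosine kinase gene Epha2 fell by 2.78 ± 0.57, Phlda1 fell by 2.29 ± 0.43 and the immediate early gene Egr1 from 1339 ± 350 to 427 ± 233 (-1.69 ± 0.38). Of the 15 growth factors, cytokines and chemokines 8 fell and 1 rose (Vegfa), 10 and 2 adjusted over the list alone (camera adjusted p = 0.000116, adjusted p = 0.078 with an estimated correlation), with Ptgs2 at -3.73 ± 0.41, Ereg at -3.65 ± 0.52 and Cxcl2 at -3.51 ± 0.47. The rise of Vegfa in this list was no longer called (0 genes) without KSR1 replicate 2, KSR1 replicate 3 or double-line replicate 2. Of 34 collagen and matrix genes 13 fell and 3 rose (camera adjusted p = 0.0456, adjusted p = 0.533 with an estimated correlation), 15 lower and 3 higher adjusted over the list alone. The proteoglycan gene Bgn fell by 2.87 ± 0.65, whereas Col4a1 (+3.48 ± 0.28) and Col6a3 (+2.72 ± 0.22) rose. The collagen call ended without KSR1 replicate 1 (0.17, 8 genes) or double-line replicate 3 (0.126, 8 genes) and with replicates 2 and 3 alone (0.0641), and 8 genes fell without KSR1 replicate 2.

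Further lists shifted in this comparison. The fibroblast markers fell in 4 of 9 genes (camera adjusted p = 0.00394, adjusted p = 0.153 with an estimated correlation), including the surface antigen gene Cd34 (-3.77 ± 0.37). Smooth muscle and SRF-regulated genes fell in 4 of 18 (camera adjusted p = 0.00326, adjusted p = 0.228 with an estimated correlation), among them Ccn2 (-3.16 ± 0.47), and in 2 of 18 without KSR1 replicate 3. S phase genes fell in 6 of 26 (camera adjusted p = 0.000116, adjusted p = 0.375 with an estimated correlation) and mitosis genes in 5 of 26 (0.00175, adjusted p = 0.375 with an estimated correlation). The S phase count was 3 without H-RasV12 replicate 3 or double-line replicate 1, 1 without KSR1 replicate 3, and 0 without KSR1 replicate 2 or double-line replicate 2. The mitosis count was 3, 2, 3 and 1 without KSR1 replicate 1, KSR1 replicate 2, and double-line replicates 1 and 2. Under median centring both counts were 3. The mesenchymal and epithelial list fell in 4 of 12 and rose in 1, Krt19 (0.00438, adjusted p = 0.078 with an estimated correlation), and the neural and glial markers fell in 3 of 6 (Gap43, Map2 and Nes) and rose in 1, Ncam1 (0.0217, adjusted p = 0.0978 with an estimated correlation). The unfolded protein and ATF4 response genes rose in 4 of 17 (0.0185, adjusted p = 0.28 with an estimated correlation, 0.0594 after quantile normalization). The interferon genes rose in 3 of 12 and fell in 1 (0.0456, adjusted p = 0.532 with an estimated correlation), a call lost under median centring (0.0572) and without KSR1 replicate 2, KSR1 replicate 3, or double-line replicate 1 or 2 (0.0639, 0.108, 0.109 and 0.108). Adjusted over the list alone, 4 fibroblast, 6 smooth muscle, 10 S phase and 5 mitosis genes were lower, 4 mesenchymal and epithelial genes and 3 neural markers were lower with 1 higher in each, 4 unfolded protein genes were higher, and 4 interferon genes were higher with 1 lower. The interferon list had 0 genes lower without KSR1 replicate 1, KSR1 replicate 2 or double-line replicate 3.

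**Figure D3:**
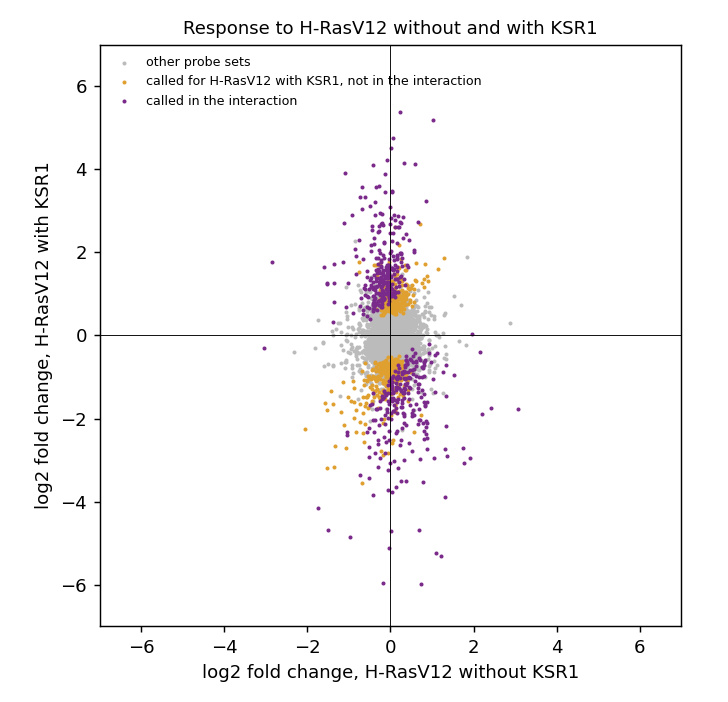
Each point is 1 of 6897 probe sets, with the log2 fold change for H-RasV12 without KSR1 on the horizontal axis and with KSR1 on the vertical axis. Purple points are the 531 probe sets called in the interaction, orange points were called for H-RasV12 with KSR1 but not in the interaction, and grey points are the others.

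KSR1 was compared in the presence of H-RasV12 with H-RasV12 alone. Of 6897 probe sets 490 rose and 532 fell, and 1838 had an unadjusted p under 0.05. Among named genes Chchd10 rose by +5.10 ± 0.35, Ctsk by +4.97 ± 0.50, the tumour necrosis factor receptor family gene Tnfrsf9 by +4.95 ± 0.43, the AMP deaminase gene Ampd3 by +4.75 ± 0.31 and Ndrg2 by +4.34 ± 0.40. Among those that fell were Postn (-4.96 ± 0.37), Thbs2 (-4.78 ± 0.41), the calcification inhibitor gene Mgp (-4.53 ± 0.63), the heparin-binding factor gene Ptn (-4.39 ± 0.40) and the fibrillar collagen gene Col1a1 (-3.88 ± 0.73). Of 34 collagen and matrix genes 19 fell and 0 rose, 20 adjusted over the list alone (camera adjusted p = 2.63e-11, adjusted p = 0.123 with an estimated correlation). Of 44 oxidative phosphorylation subunits 22 rose, 32 adjusted over the list alone (4.94e-14, adjusted p = 0.123 with an estimated correlation). The tricarboxylic acid cycle list had 12 of 16 higher, 14 adjusted over the list alone (2.85e-09, adjusted p = 0.0549 with an estimated correlation), with Mdh2 at +1.10 ± 0.18, and glycolysis had 11 of 17 higher, 12 adjusted over the list alone (4.92e-11, adjusted p = 0.107 with an estimated correlation), with the hexokinase gene Hk2 at +2.76 ± 0.22. Hypoxia-response genes rose in 7 of 12, 9 adjusted over the list alone (1.07e-07, adjusted p = 0.129 with an estimated correlation), fatty acid oxidation genes in 7 of 16, 10 adjusted over the list alone (5.67e-05, adjusted p = 0.14 with an estimated correlation), and Cycs, the cytochrome c gene, by +1.95 ± 0.29. The oxidative phosphorylation count was 14 without H-RasV12 replicate 2 and 13 without double-line replicate 2. The fatty acid oxidation count was 4, 3, 3 and 4 without H-RasV12 replicate 1, H-RasV12 replicate 2, and double-line replicates 2 and 3.

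Further lists passed in this comparison. Fibroblast markers fell in 4 of 9 (camera adjusted p = 0.00217, adjusted p = 0.14 with an estimated correlation) and smooth muscle and SRF-regulated genes in 6 of 18, with 1 higher (0.0119, adjusted p = 0.3 with an estimated correlation). Interferon genes fell in 2 of 12 and rose in 1 (0.0347, adjusted p = 0.505 with an estimated correlation), a call that ended without H-RasV12 replicate 1 (0.218) or double-line replicate 3 (0.119) and with replicates 2 and 3 alone (0.11). The number of lower interferon genes was 0 without H-RasV12 replicate 1 or double-line replicate 3, 1 without H-RasV12 replicate 3 or double-line replicate 2, after quantile normalization and with replicates 2 and 3 alone, and 4 without double-line replicate 1. The antioxidant response genes rose in 3 of 14 and fell in 1 (0.0355, adjusted p = 0.129 with an estimated correlation), and ended without H-RasV12 replicate 3 (0.0565) or double-line replicate 2 (0.0565), after quantile normalization (0.0531) and with replicates 2 and 3 alone (0.0652). It had 0 genes lower without H-RasV12 replicate 1 and with replicates 2 and 3 alone. Adjusted over the list alone, 4 fibroblast markers were lower, 7 smooth muscle genes lower and 1 higher, 6 interferon genes lower and 1 higher, and 4 antioxidant genes higher and 1 lower. Esrra rose at both probe sets (the dimmer +2.17 ± 0.31, limma adjusted p = 0.00021, and the brighter +1.61 ± 0.30, limma adjusted p = 0.00173), and Ppargc1a by +1.74 ± 0.31 (limma adjusted p = 0.00342 without a filter). The ERK target list (camera adjusted p = 0.394) and the cytokine list (0.279) did not pass, except that the ERK target list was lower without double-line replicate 1 (0.0461) and with replicates 2 and 3 alone (0.0108). The adipocyte list (0.0804) was higher without double-line replicate 3 (0.0476), and the mitosis list (0.0965) lower without H-RasV12 replicate 1 (0.0133) or double-line replicate 3 (0.00395) and after quantile normalization (0.04996).

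The interaction asked whether the response to H-RasV12 differed with KSR1. It called 531 probe sets, 287 with a higher and 244 with a lower H-RasV12 response in the presence of KSR1, and 1415 had an unadjusted p under 0.05. The largest positive differences among named genes were Chchd10 (+5.13 ± 0.50), the lipoprotein lipase gene Lpl (+4.99 ± 0.76), Adm (+4.67 ± 0.69), Ccn5 (+4.60 ± 0.39), the secreted glycoprotein gene Creg1 (+4.54 ± 0.62) and Cd68 (+4.50 ± 0.31). The largest negative were Aqp1 (-6.74 ± 0.46), Cck (-5.79 ± 0.66), Igfbp4 (-5.38 ± 0.81), Gap43 (-5.09 ± 0.32), the metalloprotease gene Adam8 (-4.88 ± 0.55) and Crabp1 (-4.83 ± 1.08). The count was 339 without H-RasV12 replicate 2 and 340 without KSR1 replicate 2. Of the 1040 probe sets called for H-RasV12 with KSR1, 490 were also called in the interaction, 490 of them in the same direction. The interaction contains that comparison, so the overlap is built in part from the same arrays. The correlation of H-RasV12 responses with and without KSR1 across probe sets was r = -0.0469 (no shared arrays), and probe sets are not independent replicates. The changes without KSR1 were small (SD 0.329, 5 probe sets called), and spread between arrays weakens such a correlation. It therefore does not show that the responses are unrelated.

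Among lists the interaction was positive for 11 of 44 oxidative phosphorylation subunits (28 adjusted over the list alone), 5 of 16 tricarboxylic acid cycle genes (12), 8 of 16 fatty acid oxidation genes (9), 6 of 17 glycolysis genes (13) and 6 of 12 hypoxia-response genes (9), with no negative call in these lists. The camera adjusted p was 9.30e-15, 1.21e-07, 1.21e-07, 4.29e-09 and 1.53e-08 in that order. With an estimated correlation the adjusted p was 0.074 for the first 4 (adjusted p = 0.074 with an estimated correlation) and 0.0961 for hypoxia. The interaction was negative for 5 of 17 ERK targets (0.000194, adjusted p = 0.122 with an estimated correlation) and 4 of 15 cytokine genes, positive for 1, Pdgfa (0.00392, adjusted p = 0.149 with an estimated correlation). It was negative for 4 of 12 mesenchymal and epithelial genes and positive for 1, Krt19 (0.00143, adjusted p = 0.074 with an estimated correlation), negative for 3 of 6 neural markers and positive for 1, Ncam1 (0.0217, adjusted p = 0.0976 with an estimated correlation), and negative for 0 of 26 S phase genes (0.000105, adjusted p = 0.377 with an estimated correlation) and 3 of 26 mitosis genes (0.00115, adjusted p = 0.377 with an estimated correlation). Adjusted over the list alone, the negative calls of these 6 lists were 6, 5, 4, 3, 0 and 6 in that order, with 1 positive call each for the cytokine, mesenchymal and epithelial, and neural lists.

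The interaction counts of several lists moved when 1 array was left out, while their camera calls did not end. The oxidative phosphorylation count was 5 without H-RasV12 replicate 2 or KSR1 replicate 2, and 6 without GFP replicate 2, GFP replicate 3 or double-line replicate 2. The tricarboxylic acid cycle count was 8 without double-line replicate 1 and 3 without any 1 of GFP replicates 2 and 3, H-RasV12 replicates 1, 2 and 3, KSR1 replicate 1 and double-line replicate 2. The fatty acid oxidation count was 3 without KSR1 replicate 2, 4 without H-RasV12 replicate 3 or double-line replicate 2, and 5 without GFP replicate 2, GFP replicate 3, H-RasV12 replicate 2 or KSR1 replicate 3. The ERK target count was 1 without H-RasV12 replicate 2, 2 without KSR1 replicate 3 or double-line replicate 3, and 3 without GFP replicate 2, GFP replicate 3, H-RasV12 replicate 3, KSR1 replicate 2 or double-line replicate 2. With replicates 2 and 3 alone it was 8, and 5 S phase genes were called. The S phase count was 1 without GFP replicate 1 and 2 without KSR1 replicate 1 or double-line replicate 3. The 1 positive cytokine gene was no longer called (0 genes) with replicates 2 and 3 alone, or without GFP replicate 2 or 3, H-RasV12 replicate 1 or 2, KSR1 replicate 1, 2 or 3, or double-line replicate 1 or 3. The mitosis count was 1 without GFP replicate 3, H-RasV12 replicate 2 or 3, KSR1 replicate 2 or 3, or double-line replicate 2.

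In the interaction 3 of the lists that missed the threshold passed it in some alternatives. The fibroblast markers (camera adjusted p = 0.0636) were negative without H-RasV12 replicate 2, KSR1 replicate 3, double-line replicate 1 or double-line replicate 2 (0.0292, 0.0431, 0.0115 and 0.0433), after quantile normalization (0.0235), under median centring (0.0493) and with replicates 2 and 3 alone (0.0316). The unfolded protein list (0.0607) was positive without H-RasV12 replicate 2, H-RasV12 replicate 3, KSR1 replicate 3 or double-line replicate 2 (0.0289, 0.0159, 0.0476 and 0.0437) and under median centring (0.0493). The p53 list (0.264) was positive without GFP replicate 1 (0.0367) and with replicates 2 and 3 alone (0.0414).

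The double line was also compared with GFP cells. Of 6897 probe sets 532 rose and 547 fell, and 1851 had an unadjusted p under 0.05. The endoplasmic reticulum protein gene Retreg1 rose by +4.50 ± 0.28, Ampd3 by +5.14 ± 0.31 and Chchd10 by +5.34 ± 0.35, whereas Postn fell by 5.88 ± 0.37. The interleukin receptor antagonist gene Il1rn fell from 10090.5 ± 4590 to 362 ± 148 (-4.69 ± 0.39), and Fmod (-4.88 ± 0.47) and Ptx3 (-4.60 ± 0.31) fell too. Of 34 collagen and matrix genes 21 fell and 1 rose (camera adjusted p = 1.01e-12, adjusted p = 0.123 with an estimated correlation, with 0 higher without GFP replicate 3, double-line replicate 1 or double-line replicate 2), of 18 smooth muscle and SRF-regulated genes 9 fell and 1 rose (8.87e-05, adjusted p = 0.127 with an estimated correlation), and of 9 fibroblast markers 6 fell (0.000247, adjusted p = 0.123 with an estimated correlation). Of the p53 targets 4 of 12 fell (0.000585, adjusted p = 0.123 with an estimated correlation), 2 without GFP replicate 3. Oxidative phosphorylation genes rose in 20 of 44, 12 without double-line replicate 2 (1.95e-11, adjusted p = 0.123 with an estimated correlation), tricarboxylic acid cycle genes in 12 of 16 (5.17e-09, adjusted p = 0.0575 with an estimated correlation), glycolysis genes in 10 of 17 (1.27e-08, adjusted p = 0.123 with an estimated correlation) and hypoxia genes in 7 of 12 (6.71e-05, adjusted p = 0.188 with an estimated correlation). Fatty acid oxidation genes rose in 5 of 16 (0.00176, adjusted p = 0.205 with an estimated correlation), and in 3, 3, 1 and 2 without GFP replicate 2, GFP replicate 3, and double-line replicates 2 and 3. Antioxidant genes rose in 4 of 14 and fell in 1 (0.0405, adjusted p = 0.123 with an estimated correlation), a call that ended without GFP replicate 1 (0.0811) or double-line replicate 2 (0.0606), after quantile normalization (0.0545) and with replicates 2 and 3 alone (0.0543). Adjusted over the list alone, 23 collagen and 9 smooth muscle genes were lower with 1 higher in each, 6 fibroblast markers and 9 p53 targets were lower, and 30 oxidative phosphorylation, 14 tricarboxylic acid cycle, 12 glycolysis, 7 hypoxia, 9 fatty acid oxidation and 4 antioxidant genes were higher, with 1 antioxidant gene lower. Of the lists that missed the threshold, adipocyte genes (0.0882) were higher without GFP replicate 3 (0.0439), mitosis genes (0.371) lower without double-line replicate 3 (0.0284), and ERK targets (0.441) lower without double-line replicate 1 (0.0461) and with replicates 2 and 3 alone (0.0267). The 5 genes that fell with H-RasV12 alone were also lower here, in a comparison that shares the GFP arrays. The fold changes of these 2 comparisons correlated with r = 0.259 across probe sets, against 0.499 for unchanged groups simulated with the shared arrays. The covariance was 0.0656 against 0.0389 simulated.

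**Figure D4:**
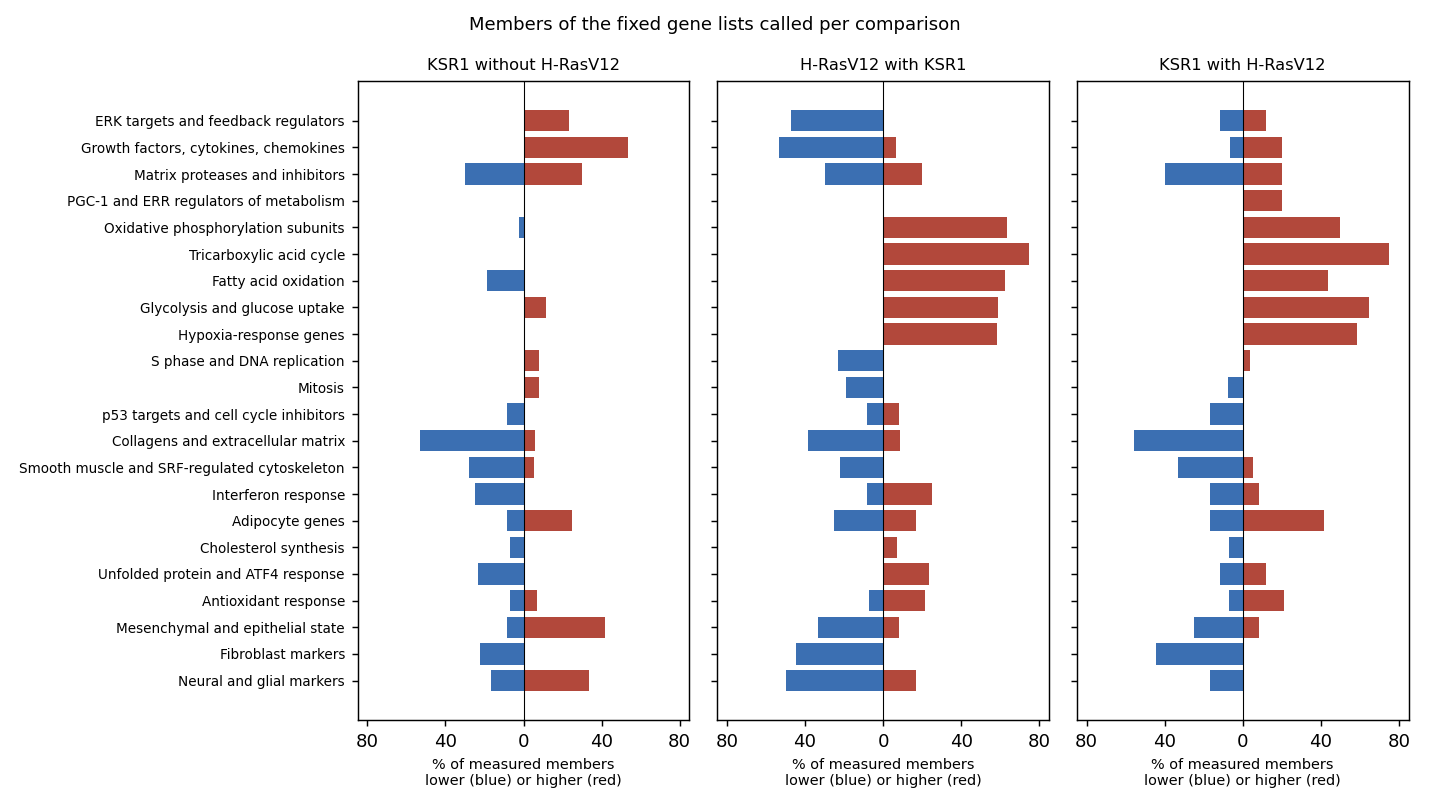
Bars give the percent of measured members of each of 22 gene lists that were called lower (blue, left) or higher (red, right) for KSR1 without H-RasV12, H-RasV12 with KSR1 and KSR1 with H-RasV12. For H-RasV12 with KSR1, 28 of 44 oxidative phosphorylation subunits were higher and 8 of 17 ERK targets were lower.

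The effects of KSR1 with and without H-RasV12 used no shared arrays. Of 813 probe sets called for KSR1 without H-RasV12 and 1022 called with H-RasV12, 327 were shared and 281 of these moved the same way, against 24.4 rises and 36.3 falls expected from independent lists. KSR1 without H-RasV12 and H-RasV12 with KSR1 share the KSR1 arrays. They shared 335 probe sets, of which 292 moved in opposite directions, against 23.7 and 38.4 expected from independent lists. Their fold changes correlated with r = -0.427 across probe sets, and unchanged groups simulated with the shared arrays gave r = -0.499. The covariance was -0.221 against -0.0388 simulated. With 3 KSR1 arrays the controls could not be split, and part of the excess may come from the shared arrays. Part may also reflect the lower mean Ksr1 signal of the double line, which was not tested.

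The cholesterol synthesis list (camera adjusted p from 0.213 to 0.95) and the PGC-1 and ERR regulators (0.485 to 0.95) did not pass in the 6 comparisons. Cholesterol synthesis passed for H-RasV12 without KSR1, higher, without GFP replicate 3 (0.0133) or H-RasV12 replicate 3 (0.0323), and for KSR1 without H-RasV12, lower, with replicates 2 and 3 alone (0.0388). The matrix proteases and inhibitors had members moving both ways (0.131 to 0.888). With KSR1 alone 3 of 10 rose and 3 fell, with the metalloprotease gene Adam8 at +3.27 ± 0.39 and Reck, a membrane inhibitor of metalloproteases, at -2.99 ± 0.35 (limma adjusted p = 5.97e-05 and 6.05e-05). The leukocyte and macrophage, endothelial, skeletal muscle and sex-linked lists had 3, 2, 4 and 1 measured genes and were not tested as lists.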

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

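The tests on the spread of the arrays, on the activity of H-RasV12 and on the history of the lines were chosen after the result was seen, and the other tests before. Groups of 3 arrays are too small for a search for single deviating samples.

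For 53 of 88 named genes the response to H-RasV12 differed between cells with and without KSR1 (limma interaction, adjusted p under 0.05), given here as the log2 difference of the responses. The count of 88 did not exclude genes below the filter, which had no test in this fit. The genes were named for large changes, in part in the interaction itself or after their values were seen, so that share follows from the choice, and over all probe sets 531 of 6897 were called. The response was higher with KSR1 for Chchd10 (+5.13), Lpl (+4.99), Adm (+4.67), Ccn5 (+4.60), Creg1 (+4.54), Cd68 (+4.50), Ctsk (+4.30), Peg3 (+3.83) and Tgfbi (+3.52). Smaller positive differences were those of Col4a1 (+3.44), Bnip3 (+2.92), Ero1a (+2.82), Fmod (+2.74), Pfkp (+2.69), Eno2 (+2.51), Cxcl12 (+2.50), Ndrg1 (+2.49) and Rragd (+2.31). They were followed by Ndrg2 (+2.18), Col6a3 (+2.06), Lipa (+2.02), Hadhb (+1.76), Esrra (+1.74), Decr1 (+1.72), Acaa2 (+1.70), Pdhb (+1.62) and Hk2 (+1.61). The smallest were Npc1 (+1.61), Ndufs3 (+1.53), Atp5o (+1.52), Sdhd (+1.34), Idh3a (+1.28), Mdh2 (+0.99) and Ctsb (+0.94). The response was lower with KSR1 for Aqp1 (-6.74), Cck (-5.79), Igfbp4 (-5.38), Gap43 (-5.09), Adam8 (-4.88), Crabp1 (-4.83), Uchl1 (-4.72) and Cxcl2 (-3.90). Smaller negative differences were those of Fst (-3.89), Cd34 (-3.80), Ereg (-3.79), Ramp3 (-3.69), Ptgs2 (-3.67), Msln (-2.46), Phlda1 (-2.44) and Egr1 (-2.16). The list of lower responses closed with Meg3 (-1.54), Prc1 (-1.45) and Plaur (-1.44). A difference can stem from either response, given here without and with KSR1. Fmod changed by -3.04 and -0.29, Ccn5 by -2.85 and +1.76, Crabp1 by +3.07 and -1.77, and Adam8 by +1.92 and -2.96. For others, such as Chchd10 (+0.24 and +5.37), the difference lay mainly in the response with KSR1. The Esrra value is that of its dimmer probe set, and its brighter one was not called in the interaction.

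For 11 gene lists the response also differed (camera, preset correlation), and 0 of them passed with an estimated correlation. The median log2 difference was positive for oxidative phosphorylation subunits (+0.89), tricarboxylic acid cycle (+0.82), fatty acid oxidation (+0.99), glycolysis and glucose uptake (+0.97) and hypoxia-response genes (+1.64). It was negative for ERK targets (-0.84), growth factors, cytokines and chemokines (-1.33), S phase and DNA replication (-0.62), mitosis (-0.39), mesenchymal and epithelial state (-0.73) and neural and glial markers (-1.30).

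The 17 mouse control probe sets, which are outside the main measurement, were fitted apart and adjusted over these 17. That for the 3' end of the transferrin receptor was higher with KSR1 than with GFP by 2.16 on the log2 scale (limma adjusted p = 0.026). Its 5' end was at +1.90 and missed the threshold (limma adjusted p = 0.0544). In the double line against GFP the 2 ends were at +1.91 and +1.47 and also missed it (limma adjusted p = 0.0608 and 0.137).

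H-RasV12 changed 5 probe sets without KSR1 and 1040 with it. A larger spread between arrays without KSR1 is argued against by the SDs of the arrays from their group means. These were 0.238 to 0.357 without KSR1 and 0.267 to 0.394 with it. The SDs of the log2 fold changes were at least 1.936 times as large with KSR1 over the full set and each array left out. That ratio cannot decide on the spread, since 1 fit gave both comparisons the same error per probe set and the ratio restates the larger changes. GFP replicate 1, the array whose removal raised the count most, is argued against by the count without it, 23. It stays open whether H-RasV12 was inactive in the line without KSR1, where the ERK target list did not pass (camera adjusted p = 0.941). That list cannot decide it, since with KSR1 present 0 of its 17 genes rose with H-RasV12 and 8 fell. The Hras transcript was not analysed here. It also stays open what part the history of the lines or their Ksr1 levels may have, since the labels name 1 cell line per condition.

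Of the 10 splits of the 6 arrays 1 gave as many probe sets for H-RasV12 without KSR1 (5, highest other 0), KSR1 without H-RasV12 (813, 0), H-RasV12 with KSR1 (1040, 0), KSR1 with H-RasV12 (1022, 0) and both transgenes (1079, 1), and 10 splits are too few for a share under 0.05. Where the replicate numbers pair the arrays, for KSR1 without H-RasV12 and H-RasV12 with KSR1, the other splits that part all 3 pairs are among those that called 0. For the interaction 1 of 100 drawn splits of the 12 arrays, the real one, gave as many probe sets (531, highest other 323). These splits also mix the lines with and without KSR1, which puts the KSR1 differences into the spread, so they do not settle whether chance is excluded for the interaction.

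Cd68 and Ctsk rose with H-RasV12 in cells with KSR1. Leukocytes in the culture, which would raise their other transcripts along with Cd68, are argued against by the other 13 leukocyte markers. This holds only as far as their probe sets can respond. In the fit without a filter their median log2 fold change was -0.53 (SD 0.33 over markers, highest +0.04), against +4.51 for Cd68. In that fit 0 were called higher and 2 lower, Adgre1 (24.8 to 8.08) and Mrc1 (41.2 to 6.41), both near the floor. Of the 13 markers 11 lay below the filter, where a probe set that does not respond would show no rise either. The 2 above it, Cd14 and Laptm5, were at -0.60 and -0.28, and Cd14 already read 1126 ± 210 with GFP. A candidate explanation is a rise of lysosome genes together, as of 35 lysosome and autophagy genes not seen before the test 14 rose and 0 fell (camera p = 2.33e-08, p = 0.0625 with an estimated correlation). Their median log2 fold change was +0.46, so a shared rise of that size falls short of the change of Cd68. What drives such a rise was not tested.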

How the results depend on the processing

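The analysis of replicates 2 and 3 alone was chosen after the data were seen, and the other alternatives before. Of 389 named-gene results past the threshold, run under up to 23 alternatives each (8881 values), 8282 stayed past it, 599 kept their direction and missed it, and 0 changed sign. For H-RasV12 without KSR1 (5 probe sets) the count was 8 with no filter, 56 with array weights, 2 with the compared groups alone, 53 with replicates 2 and 3 alone, and 1 to 23 when 1 array was left out. At an adjusted p under 0.01 the counts were 1, 420, 562, 581, 213 and 614 for H-RasV12 without KSR1, KSR1 without H-RasV12, H-RasV12 with KSR1, KSR1 with H-RasV12, the interaction and both transgenes. An absolute log2 fold change of at least 1 left 512, 616, 641 and 651 for KSR1 without H-RasV12, H-RasV12 with KSR1, KSR1 with H-RasV12 and both transgenes. These drops follow from the stricter thresholds. The interaction count was 801 with array weights. Leaving out 1 array gave 482 to 934 probe sets for KSR1 without H-RasV12 and 339 to 679 for the interaction. With the estimated correlation 0 lists were called in any comparison. The cause of the other shifts was not tested. Over all groups 13 of 18 pairs of arrays with the same number correlated above 0.1 in their deviations from the group means, and 10 of 12 arrays correlated best with their own number. For H-RasV12 without KSR1, KSR1 with H-RasV12 and both transgenes 1, 1 and 2 of the 3 pairs did, so the numbers were not taken to pair the arrays there. For both transgenes the lowest pair was at r = 0.0994, so that choice rests on the cutoff. Pairs of arrays with different numbers reached r = 0.2415, so the evidence for pairing is limited. With the block the growth factor and cytokine list was lower for H-RasV12 without KSR1 (camera adjusted p = 0.0322), 6 interferon genes were lower for KSR1 with H-RasV12, 7 p53 targets were lower with both transgenes, and the interaction called 23 oxidative phosphorylation, 10 tricarboxylic acid cycle, 10 glycolysis and 1 S phase genes. With the replicate number as a block the counts were 10, 1047, 1290, 1265, 741 and 1317 in the order above, and none of the named-gene calls was lost. In the paired comparisons, KSR1 without H-RasV12 and H-RasV12 with KSR1, the block changed no call of a named gene or list except those of Esrra and the unfolded protein list given there. MAS5 signals near the floor limit the fold changes of dim probe sets, as the pseudocount of 23 does.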

Other observations

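The tests on lysosome and imprinted genes used lists written after some members had been seen, and those members were left out of the tests. The lysosome genes that rose with H-RasV12 in cells with KSR1 included the acid lipase gene Lipa (+1.87 ± 0.35, limma adjusted p = 0.00178) and the cholesterol transporter gene Npc1 (+1.58 ± 0.19, limma adjusted p = 6.17e-05). The transcription factor gene Mitf (+2.60 ± 0.56, limma adjusted p = 0.00561) and the Rag GTPase gene Rragd (+2.05 ± 0.37, limma adjusted p = 0.00143) also rose, and were among the members seen before. The Mitf signal varied widely in the double line, at 1107 ± 1007 against 128 ± 51.8 with KSR1. Of the 35 unseen genes 0 were called for H-RasV12 without KSR1, 11 rose with KSR1 in the presence of H-RasV12 and 9 had a positive interaction. For KSR1 without H-RasV12 the set was lower (camera p = 0.00504, p = 0.31 with an estimated correlation), with 0 higher and 2 lower, Atp6v0d1 and Lamp2. With both transgenes against GFP 8 were higher and 1, Npc2, was lower (camera p = 0.000676, p = 0.225 with an estimated correlation). Some of the 14 rises with H-RasV12 in cells with KSR1 therefore started from a level below that of GFP cells, as for Lamp2 (3298 with GFP, 1470 with KSR1 and 2614 in the double line) and Atp6v0d1 (2419, 1072 and 2098).

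Several imprinted genes were lower with KSR1 than with GFP. Meg3, a long noncoding RNA, fell from 1082 ± 5.42 to 171 ± 56.2 (-2.55 ± 0.27, limma adjusted p = 2.94e-05), and Mest (-3.41 ± 0.61) and Ndn (-3.24 ± 0.51) fell as well. The Mest signal varied widely with GFP, at 946 ± 867 against 47.2 ± 24.2 with KSR1. Of all 17 measured imprinted genes 8 were lower and 0 higher, and these include the genes that drew attention to the class. A hypothesis is that imprinted genes may differ as a class between these lines. Over the 11 members not seen before the test, the median absolute log2 fold change for KSR1 against GFP, the comparison the test was set for, lay above 76.82% of 10000 random lists matched on signal, short of the 95% asked for. In the other 5 of 6 comparisons it lay above 98.96% for H-RasV12 without KSR1 (permutation p = 0.0105 over the random lists, 0.063 adjusted over the 6 comparisons, with 0 of 11 called), 82.89% for H-RasV12 with KSR1, 56.9% for KSR1 with H-RasV12, 74.11% for the interaction and 86.75% for both transgenes. The hypothesis stays open.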
